A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

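The series holds 2 one-colour (Cy3) arrays of a custom Agilent yeast design, 1 for the wild type and 1 for the strain without APP1, PAH1, DPP1 and LPP1. Per the labels' protocols, RNA was extracted with TRIzol and glass beads, copied with an oligo-dT primer carrying a T7 promoter, amplified and labelled with Cy3. Groups were taken from the genotype labels. Both arrays lay on the same slide, so slide and genotype were not confounded.

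The scanner files hold spot intensity values made with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed intensity in these deposited files had been background-subtracted and detrended within each array, per the file headers, and had not been normalized between arrays. The mean and local background intensity deposited beside it were raw. The authors also deposited a table with a log2 value for every gene name, whose processing is not given in the sources used here. Set against the scanner values, that log2 table deposited by the authors equalled the log2 processed signal minus a constant of 11.90 for the wild type and 11.54 for the mutant. It correlated across 6043 matched genes with r = 1.00 for each array, its 75th percentiles were 0.01 and 0.00, and its medians were -1.27 and -1.42. Its scale, centring and direction were thereby settled.

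Each array had 15744 spots, of which 536 were controls. The 15208 other spots belonged to 6256 probes, 3560 with 2 spots and 2696 with 3. In the main setting the log2 processed signal was taken relative to the 75th percentile of the non-control spots, a signal of 3758 on the wild-type array and 2962 on the mutant array. Control spots were left out, as were 183 wild-type and 196 mutant spots with a non-uniformity or population outlier flag. Spots of a probe were averaged and probes of a gene were averaged. A probe counted as measured when at least 50% of its spots were well above background on both arrays and it was not saturated on both. Each array had 91 saturated spots. A further 25 genes were saturated on 1 array only, 13 on the wild-type and 12 on the mutant array. They stayed in the counts and lists at their measured value, 8 of them among the genes higher and 4 among those lower, and those named in the text are given as bounds. Of 6227 genes, 6199 had 1 probe and 28 had several. The 27 measured genes with several probes had a median range of 0.17 log2 units between probes and a highest range of 1.03, and 2 had probes of opposite sign.

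Measured genes numbered 6046. A further 52 were not well above background in the mutant only, 19 in the wild type only and 84 in both. Another 21 were saturated on both arrays. For 5 (PGK1, HXT7, HXT6, HXT3 and ALD4), no probe had an unflagged spot on both arrays. For a gene dim on 1 array, the bright value was set against the higher of the dim probe's own value and the lowest value among probes well above background on the dim array. The result is given as at least N-fold. It exceeded 1 for 46 genes lower and 19 genes higher in the mutant, of which 26 and 15 reached 2-fold. Repeated spots had a median SD of 0.04 on each array, and the median SE of a log2 ratio from spots was 0.05, with a 95th percentile of 0.16. With 1 array per genotype, the number of arrays limits the precision, and no spread between cultures could be estimated.

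Gene names come from the files, updated through a RefSeq table of assembly R64, in which 5738 of the 6227 systematic names matched. The other 489 kept the name in the file. Coordinates are those of the array design, build sacCer1 per the file headers.

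The 2-fold limit, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. Genes with an absolute log2 ratio of at least 1 were counted. For each of 47 lists the median log2 ratio was ranked among 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A list stood apart at or above the 97.5th or at or below the 2.5th percentile, if it had at least 4 measured members. Named genes are the deleted and marker genes, the 12 highest and 12 lowest ratios among genes with a standard name, the 4 largest absolute ratios of each list and the 4 largest bounds per direction. The 12 highest and lowest exclude the deleted and marker genes and had to keep their sign in every probe and an absolute ratio of at least 1 with normexp. Of the list members so defined, the text gives those most distant from 0. It adds DGA1, SPI1 and SER1, chosen after their values were seen, and STE6, BAR1 and AGA2 from a test in the closing part. Some genes that this rule names are not reported here.

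Alternatives were normexp background correction (offset 50), median scaling, quantile and cyclic loess normalization, no filter on dim probes, a stricter filter that also removed the dimmest 25% of measured probes, the median over probes, the authors' table, unmatched random lists and lists restricted to genes whose probes agree in sign. Scaling on 6 spike-in probes and keeping flagged spots were added after the data were seen. The spike-in probes were lower on the mutant array by a mean log2 of -0.60 (SD 0.10), against -0.34 for the 75th percentile.

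Before use, the steps were tested on simulated arrays of 6046 genes in which 200 single genes and 10 lists of 20 genes changed. All 50 genes at each of 1.50, -1.50, 3.00 and -3.00 passed the 2-fold limit, with median recovered ratios of 1.43, -1.55, 2.92 and -3.07. Changed genes were given spot noise only, with no scatter between arrays and no dim or saturated probes, so this checks the arithmetic and not the sensitivity. Of 5646 unchanged genes, 96 (1.70%) passed the limit, given the scatter between arrays that the simulation assumed. That scatter was smaller than the SD of the real ratios, 0.84, so 1.70% is no false rate for these arrays. All 10 lists, with an added shift of 0.50, stood apart, as did 2.50% of 200 unchanged lists. The work used R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.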

Results

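Steady-state RNA of budding yeast was measured on 2 one-colour Agilent arrays, 1 per genotype. The wild type was W303-1A, a common laboratory strain. The other strain, called the mutant here, lacked APP1, PAH1, DPP1 and LPP1, which together encode the phosphatidate phosphatases of yeast. These enzymes convert phosphatidate to diacylglycerol, the precursor of triacylglycerol and of phospholipids made through the CDP-choline and CDP-ethanolamine routes. Both cultures were described as being in stationary phase and had grown for 24 h at 30 °C in minimal medium with 2% glucose. The comparison set the transcriptome of stationary cells lacking all 4 genes against that of the wild type. The arrays also differed in marker, mating-type and mitochondrially encoded RNA, as given below. Whether the other differences go with these or with the 4 deletions cannot be told apart here. There were no replicate cultures, so no test was made, and every difference below is a difference between these 2 arrays. The error given with a gene is the standard error (SE) over repeated spots and covers technical spread only. Values are log2 signals relative to the 75th percentile of the array, and changes are mutant minus wild type. The share of spots well above background was 98.2% for the wild type and 97.6% for the mutant. Of 6227 genes on the array, 6046 were measured on both arrays.

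The deleted genes were examined first. APP1 (YNL094W), DPP1 (YDR284C) and LPP1 (YDR503C) were well above background in the wild type and not well above background in the mutant. APP1 was at least 135-fold lower, DPP1 at least 3034-fold lower and LPP1 at least 355-fold lower. PAH1 (YMR165C) differed by -2.84 on the log2 scale (SE 0.07), and its signal remained measurable in the mutant at -2.22, against 0.62 in the wild type. In the coordinates of the array design, genome build sacCer1, the PAH1 probe covers chromosome XIII 590079 to 590138. The APP1 probe covers chromosome XIV 449217 to 449276, the DPP1 probe chromosome IV 1030691 to 1030750 and the LPP1 probe chromosome IV 1455035 to 1455094. The interval removed from each gene is not given in the sources used here, so the PAH1 signal alone does not check the label.

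Among 7 genes commonly used as selectable markers, 4 were at least 2-fold higher in the mutant. HIS3, of histidine synthesis, was higher by 3.19 (SE 0.01), URA3, of uracil synthesis, by 3.12 (SE 0.01), TRP1, of tryptophan synthesis, by 1.97 (SE 0.03) and ADE2, of adenine synthesis, by 1.60 (SE 0.04). LEU2 at -0.50, LYS2 at -0.71 and MET17 at 0.13 lay within 2-fold. The list median was 1.60, above its random range as defined for the gene lists below. This median is the value of ADE2. The purine synthesis list, which does not hold ADE2, also had a median of 1.60, so ADE2 was not set apart from its pathway.

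**Figure D1:**
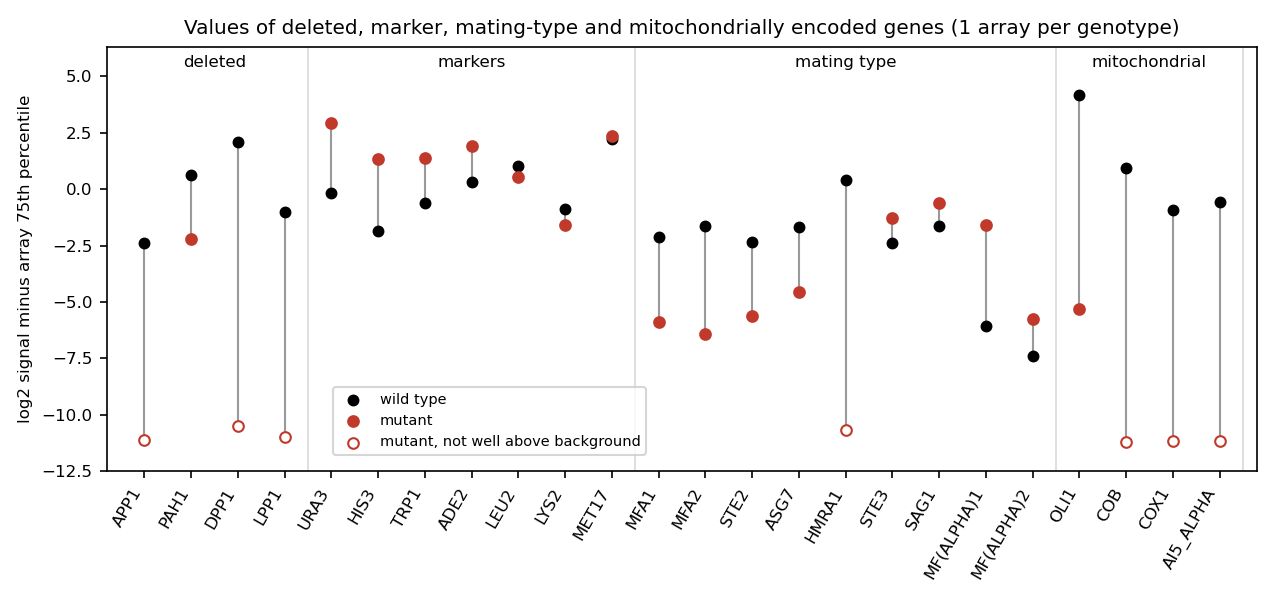
Array values (log2 signal minus the 75th percentile of the array) of the deleted genes, marker genes, mating-type genes and 4 mitochondrially encoded genes, with filled black points for the wild type, red for the mutant and open red for mutant probes not well above background; each point is 1 array. APP1, DPP1 and LPP1 end in open points while PAH1 stays measurable at -2.22, and URA3 lies at 2.95 in the mutant against -0.16 in the wild type.

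Across the measured genes, 474 were at least 2-fold higher and 592 at least 2-fold lower in the mutant, so 44.5% of these genes were higher. At the 4-fold level, 84 were higher and 74 lower. The values of the arrays correlated across genes with r = 0.939, where genes are not independent replicates. The balance of the directions depended on how the arrays were scaled. The higher share was 61.2% with median scaling, 56.0% with quantile normalization, 57.4% with cyclic loess normalization and 69.0% when the arrays were scaled on spike-in probes. The median gene lay at -0.12 in the main setting, and these scalings moved it by 0.17, 0.10, 0.11 and 0.26.

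Among measured genes with a standard name, RGI2, a gene of respiratory growth, had the highest ratio, 10.55 (SE 0.07), from -6.97 to 3.58. PHO89, a phosphate transporter, was higher by 6.55 (SE 0.08) and HXT2, a high-affinity glucose transporter, by 6.20 (SE 0.03). The mutant signal of HXT2 was not flagged as saturated but was as high as that of the dimmest saturated spots, so its difference could be larger. SPL2, a regulator of low-affinity phosphate transport, was 32.0-fold higher, from -3.10 to 1.90 (SE 0.05). REG2, a regulatory subunit of the Glc7 phosphatase, was higher by 4.78, the alpha-factor gene MF(ALPHA)1 by 4.50, YIG1 by 4.35 and the kinase gene MRK1 by 4.30. The acetate transporter gene ADY2 was higher by 4.30, the gluconeogenic gene PCK1 by 3.96, INO1, which encodes inositol-3-phosphate synthase, by 3.83 and the invertase gene SUC2 by 3.63.

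Among genes with a signal on both arrays, the lowest ratio belonged to OLI1, the mitochondrially encoded subunit c of ATP synthase. Its wild-type probe was saturated, so the difference is a bound, at least 709-fold lower in the mutant, where it was at -5.32. The minor pyruvate decarboxylase gene PDC6 differed by -5.08 (SE 0.04), the a-factor genes MFA2 by -4.77 (SE 0.20) and MFA1 by -3.80, and the cytosolic catalase gene CTT1 by -4.02 (SE 0.11). The adenine deaminase gene AAH1 was at -3.86, HMS1 at -3.50, YRO2 at -3.48, SPS100 at -3.32, the alpha-factor receptor gene STE2 at -3.30, SET6 at -3.25 and the ribosome assembly gene MAK16 at -3.15. Normexp, whose offset shrinks dim signals, moved several of these values: RGI2 to 8.98, MF(ALPHA)1 to 3.62, MFA2 to -3.45, MFA1 to -2.81, HMS1 to -2.68, STE2 to -2.49 and SET6 to -1.69.

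**Figure D2:**
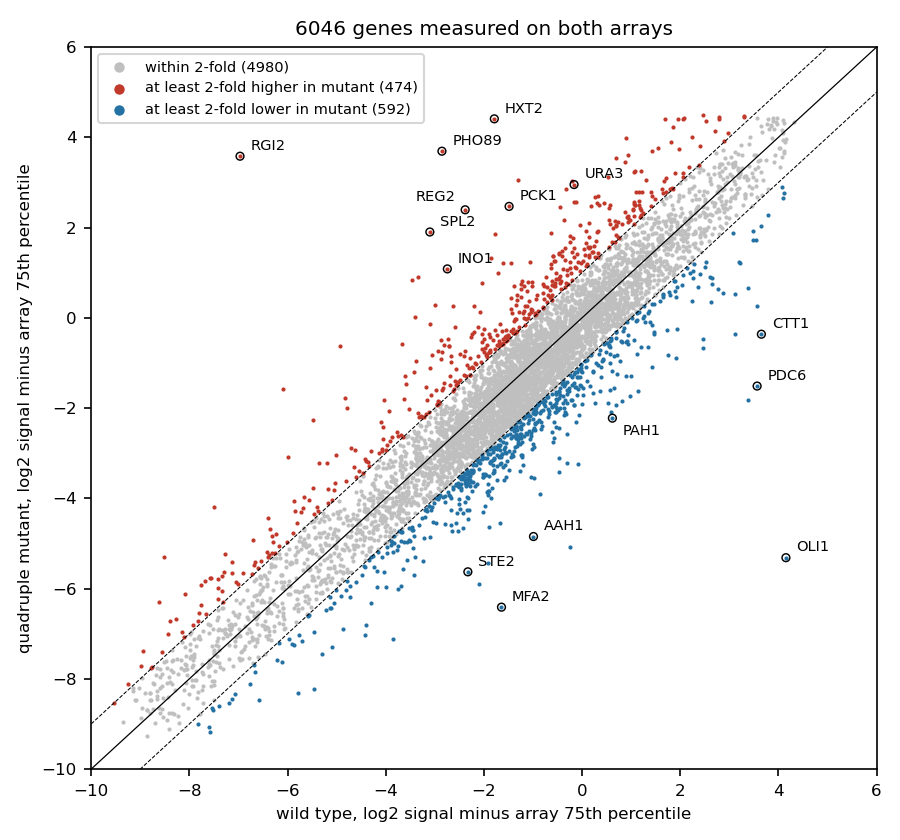
Each of 6046 measured genes, with the wild-type value on the x axis and the mutant value on the y axis (log2 signal minus the 75th percentile of the array); the solid line marks equality and the dashed lines 2-fold. The 474 red points lie at least 2-fold above and the 592 blue points at least 2-fold below, and RGI2 and OLI1, the latter at a saturated wild-type value, are farthest from the line.

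Gene lists fixed beforehand were set against random lists of the same size and expression. Of 46 lists with enough members, 12 had a median above the random range, at percentiles from 99.0 to 100, and 9 had a median below it, at percentiles from 0 to 1.60. Random lists would fall outside in 5% of cases, but their genes were drawn singly. Lists whose members vary together between cultures would fall outside more often, so 5% is no false rate for the lists here. The number of members past 2-fold depended on the scaling in several lists, since many members lay near that limit. None of these 21 medians changed sign under 5 other ways of scaling or background correction.

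Phospholipid genes controlled by the inositol-sensitive promoter element UASINO were higher in the mutant. Their median was 1.02, with 8 of 15 members at least 2-fold higher and 0 lower. After INO1, the largest values were those of the inositol transporter gene ITR1 at 2.58, the phosphatidylserine synthase gene CHO1 at 2.24 and the activator gene INO2 at 1.98. Among 8 regulators of inositol response and of Pah1, the repressor gene OPI1 was at 1.89 and the activator gene INO4 at 1.29, while the list median was -0.08. Genes of the CDP-choline and CDP-ethanolamine routes had a median of 0.36 at percentile 95.8, inside the random range, with 2 of 8 at least 2-fold higher: the choline transporter gene HNM1, 2.38-fold higher, and the choline kinase gene CKI1 at 1.02.

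The synthesis of storage lipids and fatty acids did not stand apart. Triacylglycerol and steryl ester genes had a median of 0.01, at percentile 72.5. The glycerol-phosphate acyltransferase genes SCT1 at 1.11 and GPT2 at 1.06 were the 2 of 10 members at least 2-fold higher, and 0 were lower. GPT2 lay at the 2-fold limit with normexp. The diacylglycerol acyltransferase gene DGA1 was at -0.16. Lipid droplet lipases and proteins had a median of 0.07 and none of 15 members reached 2-fold; SCS3 came closest at 0.98 and was at 1.15 with median scaling. Fatty acid synthesis, elongation and desaturation had a median of -0.29 at percentile 16.6, with the acyl-CoA synthetase gene FAA1 at 1.35, and FAA3 at -1.08 and ELO1 at -1.03. Those last 2 values passed the 2-fold limit only narrowly, and each was within it under normexp and under each other scaling tried.

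Ergosterol synthesis was lower, with a median of -0.52 and 6 of 25 members at least 2-fold lower. With spike-in scaling the median was -0.26 and 2 members were lower, ERG5 and ERG25, while 2 others were at least 2-fold higher, against 0 higher in the main setting. ERG5 was at -3.04, the methyl sterol oxidase gene ERG25 at -2.27, ERG3 at -1.25 and ERG13 at -1.21. Sphingolipid genes had a median of -0.21 inside the random range, with CSH1 at -1.93 and LAG1 at -1.25 lower, and SUR1 at 1.41 and ORM2 at 1.21 higher. None of 17 phospholipase and phosphoinositide genes reached 2-fold, and their median was -0.13.

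Peroxisomal beta-oxidation was higher, with a median of 1.15 and 10 of 18 members at least 2-fold higher. The acyl-CoA oxidase gene POX1 was at 3.28, ECI1 at 2.70, FOX2 at 2.67 and SPS19 at 2.16. Peroxisome biogenesis genes had a median of 0.14 at percentile 96.0, inside the random range, with PEX21 at -1.20 the only 1 of 24 to reach 2-fold.

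Carbon metabolism showed mixed values. Genes of gluconeogenesis, the glyoxylate cycle and acetate use had a median of 0.44, with 6 of 21 at least 2-fold higher and 3 lower. Beside ADY2 and PCK1, the alcohol dehydrogenase gene ADH2 was at 2.81, whereas the isocitrate lyase gene ICL1 was at -2.63. Hexose transport and sensing had a median of 0.58, with 9 of 20 higher and 2 lower. HXT2 led this list, MAL31 was at 2.09, the glucose-signalling gene MTH1 at 1.84 and the repressor gene MIG2 at -2.19. Glycolysis and fermentation had a median of -0.49 over the 17 of 25 members that could be measured. PDC6 was the lowest, whereas the hexokinase-type gene GLK1 at 1.77 and the alcohol dehydrogenase gene ADH5 at 2.04 were higher. The hexokinase gene HXK1, saturated in the mutant, was at least 5.44-fold higher. The other 8 members were saturated on both arrays or lacked an unflagged spot on at least 1 array. The median therefore leaves out the brightest glycolytic genes. Including the saturated genes ended the call (0.028 from its random median), but saturation fixes their ratios near the difference in scaling, so this decides nothing. The list did not stand apart against random lists not matched on expression. The gluconeogenesis list fell inside the random range under quantile and loess normalization, and the hexose list did so with the stricter filter on dim probes.

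Mitochondrial genes encoded in the nucleus differed by class. Mitochondrial ribosomal proteins had a median of 0.85, with 22 of 66 at least 2-fold higher and 0 lower, led by MRPS17 at 1.95, MRPL39 at 1.82 and MRPL28 at 1.52. The higher members numbered 36 with median and 44 with spike-in scaling. The tricarboxylic acid cycle had a median of -0.02, with CIT3 at 1.78. Respiratory chain and ATP synthase genes had a median of -0.05, with QCR9 at 1.02 and QCR8 at 1.01 just beyond 2-fold among 38 members. QCR8 was at 0.98 with normexp and QCR9 at 0.98 with quantile normalization. Among genes of the mitochondrial genome itself, COB was at least 1362-fold lower in the mutant, AI5_ALPHA at least 474-fold and COX1 at least 369-fold.

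The unfolded protein response list had a median of 0.84, with 4 of 19 at least 2-fold higher: the endoplasmic reticulum chaperone gene KAR2 at 2.08, its regulator HAC1 at 1.88, FPR2 at 1.34 and JEM1 at 1.18. With median scaling 10 members and with spike-in scaling 11 were higher. Heat shock proteins had a median of 0.94, with 11 of 24 higher and 2 lower (1 with spike-in scaling). The mitochondrial chaperonin gene HSP10 was at 2.36, BTN2 at 1.96, and the mitochondrial chaperone gene SSC1 at 1.76. HSP60, saturated in the mutant, was at least 3.14-fold higher. The Msn2 and Msn4 general stress list went the other way, with a median of -0.88 and 8 of 23 lower. After CTT1, the aldehyde dehydrogenase gene ALD3 was at -2.71, SIP18 at -2.64 and GRE2 at -2.32, while SPI1 was the 1 member at least 2-fold higher, at 2.04, against 3 members with spike-in scaling.

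Ribosome biogenesis had a median of -1.10, with 43 of 66 members at least 2-fold lower (28 with spike-in scaling) and 0 higher. Below MAK16, DBP2 was at -2.76 and UTP13 at -2.02, and the nucleolar gene NSR1 went from 3.21 to 1.21. Ribosomal proteins had a median of -0.75, with 31 of 137 lower and 0 higher, RPL7B at -2.02 and RPS30B at -1.99 being the lowest. RPL7B was at -1.11 with normexp. The lower ribosomal proteins numbered 17 with median and 12 with spike-in scaling. Cell cycle genes had a median of -0.61 with 6 of 34 lower, among them the cyclin gene CLN3 at -1.76, the transcription factor gene SWI5 at -1.66 and the daughter-cell gene DSE1 at -1.37. Amino acid synthesis under Gcn4 had a median of -0.49, with 6 of 45 lower, such as ARG3 at -2.71 and LYS9 at -2.42, and SER1 at 1.31 the 1 gene higher. Vacuolar proteases and the V-ATPase had a median of -0.41, with 3 of 21 lower, the aminopeptidase gene APE1 at -1.97 among them, and 1 lower with each other scaling. That list lay inside the range of random lists not matched on expression.

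Purine synthesis had a median of 1.60, with 9 of 16 members at least 2-fold higher and 1 lower. The one-carbon genes MTD1 at 3.19 and SHM2 at 2.85 led it, followed by ADE13 at 2.73 and ADE8 at 2.70. Sulfur and methionine genes had a median of 0.29 with 7 of 29 higher and 2 lower (1 with spike-in scaling). The sulfate transporter gene SUL1 was at 2.79, the methionine synthase gene MET6 at 1.91, SAM1 at 1.67 and MET28 at -1.91. This list fell inside the random range under quantile and loess normalization.

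Among nutrient regulons, the iron list was higher, with a median of 0.71 and 11 of 28 members at least 2-fold higher. The siderophore transporter gene SIT1 was at 3.44, the iron oxidase gene FET3 at 2.95, FIT2 at 2.40 and FRE6 at 1.98. FRE5 was not well above background in the wild type and was at least 9.10-fold higher in the mutant. The phosphate list had a median of 0.15 at percentile 92.5, with 7 of 21 higher and 3 lower. PHO89 and SPL2 were joined by PHM6 at 2.43, whereas PHM8 was 1.73 in the wild type and -0.27 in the mutant. It stood apart under quantile and loess normalization, as did the DNA damage list. Zinc genes had a median of -0.27, with ADH4 at -2.12 and MNT2 at -1.02, the latter -0.95 with normexp. Nitrogen catabolite genes and permeases had a median of 0.03, with 2 of 30 higher and 3 lower: the ammonium permease gene MEP2 at -1.77, PUT4 at -1.52 and DAL7, which went from -1.97 to -3.47, were lower. Of the higher members, AGP1 was at 1.07, or 0.96 with normexp.

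The list of a-specific and general haploid genes had a median of -0.63, with 4 of 16 members at least 2-fold lower: MFA2, MFA1, STE2 at -3.30 and ASG7 at -2.89. Of 3 further a-specific genes, named here outside the rule, STE6 at -0.46 and BAR1 at -0.23 lay within 2-fold. The third, AGA2, was not well above background in the mutant and was at least 66.4-fold lower. Since 7 of the genes that both haploid types express had a median of -0.66, the list median does not set a-specific genes apart. All 4 alpha-specific genes were at least 2-fold higher, with a median of 1.39, MF(ALPHA)1 at 4.50, MF(ALPHA)2 at 1.63, STE3 at 1.14 and SAG1 at 1.04. MF(ALPHA)2 was at 0.84 with normexp. HMRA1, the silent copy of the a1 gene, whose sequence is shared with the active copy in a cells, was at least 932-fold lower in the mutant. With the stricter filter on dim probes, the a-specific list fell inside the random range. That filter goes by the mean of both arrays, so it removes genes more readily for being low in the mutant, and the lost call decides nothing.

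The remaining lists lay inside the random range. Medians were -0.12 for oxidative stress and redox, with SRX1 at -1.67 and GPX1 at 1.52, and 0.10 for trehalose and glycogen, with GSY1 at 2.09. The stationary phase list was at -0.16, with SPG4 at 2.27, RPI1 at -1.52 and SNZ1, saturated in the mutant, at least 4.06-fold higher. Autophagy was at -0.05 with ATG15 at -1.40, and the proteasome at 0.12 with 0 of 33 beyond 2-fold. Cell wall genes were at 0.04 with CHS2 at -1.34, multidrug efflux and flippases at -0.22 with FLR1 at -2.58, and nuclear pore and envelope genes at -0.23 with BRL1 at -1.25 and SRC1 at 1.15. Histones were at -0.06, DNA damage genes at 0.13 with HUG1 at 1.78 (1.07 with normexp) and RNR2 at -1.74, meiosis genes at 0.00 with SPS100 lowest, and hypoxic genes at 0.03 with ROX1 at -1.44. Of the 25 lists inside the range, 13 had a median that changed sign under at least 1 of the 5 other settings, so no direction is given for them. The other bounds named by the rule were BSC1 at least 4.63-fold and ECM23 at least 3.13-fold higher. Ribosomal protein pairs, HXT genes and other near-identical copies can share a probe signal, and their single values are uncertain. Among named values near the limit, those of ATG15, BRL1, LAG1, PEX21, ERG3 and ERG13 were also within 2-fold in at least 1 other setting.

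**Figure D3:**
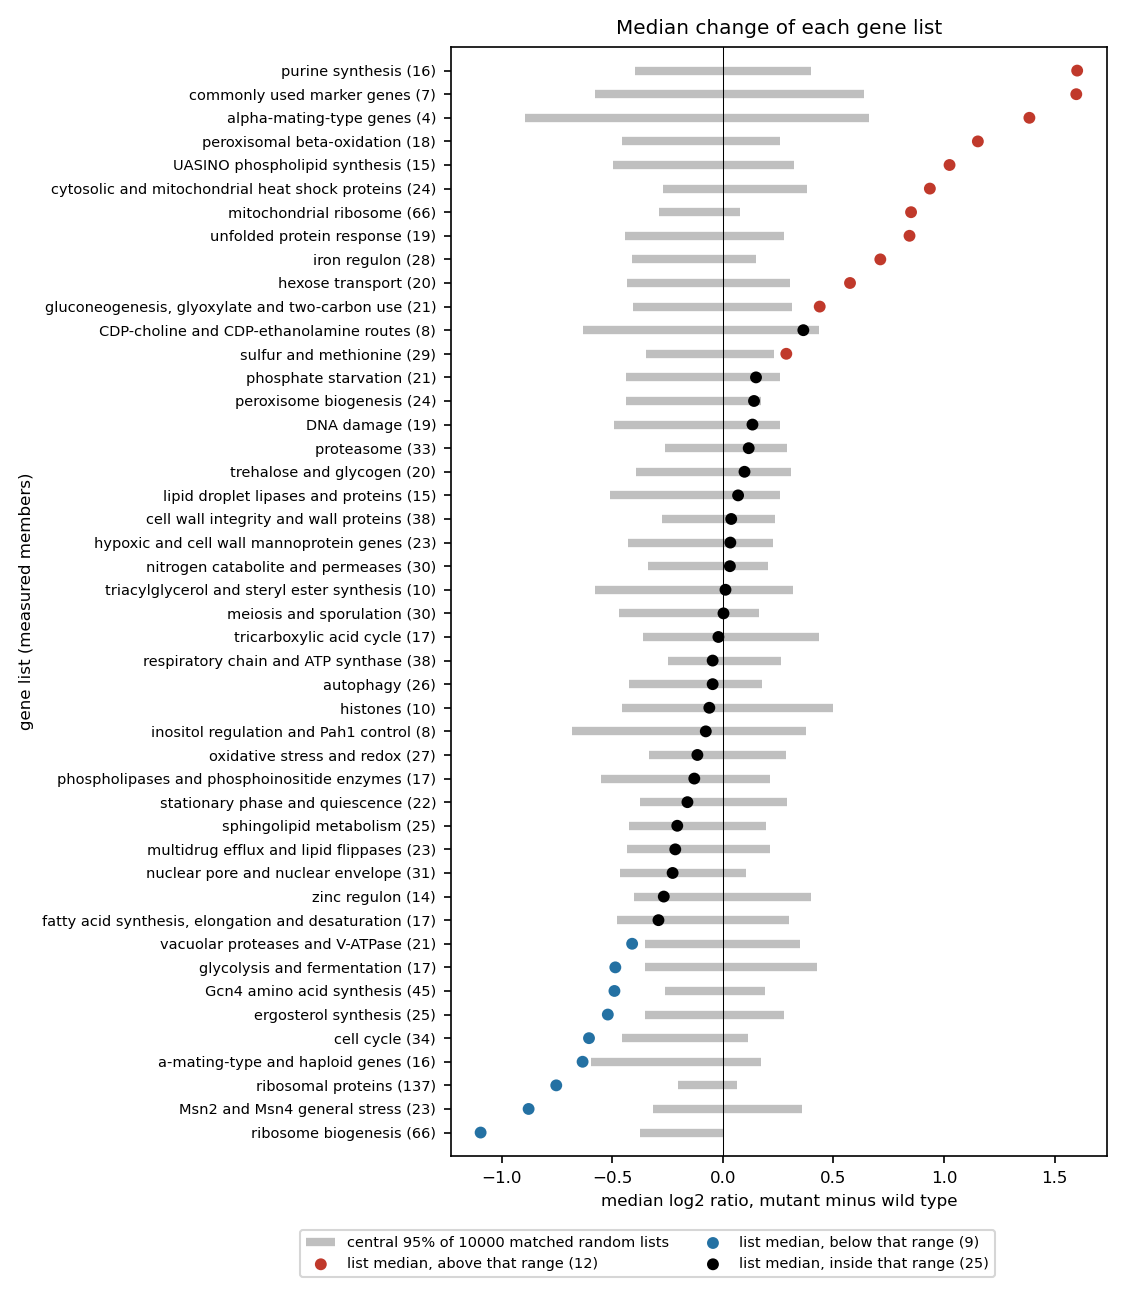
Median log2 ratio (mutant minus wild type, x axis) of the measured members of each gene list, with the number of measured members in brackets; grey bars span the central 95% of 10000 random lists matched on expression. Purine synthesis (1.60) and the UASINO list (1.02) lie above their bars, ribosome biogenesis (-1.10) lies below, and the triacylglycerol list (0.01) lies inside.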

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

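Spike-in scaling and the retention of outlier spots were chosen after seeing the data; the other alternatives were planned. Against 474 genes higher and 592 lower, spike-in scaling gave 745 and 335, and the stricter filter on dim probes gave 380 lower, having only 4548 genes to count. The counts under the other alternatives stayed within 1.5 times. Median and spike-in scaling add a constant to every ratio, so no higher call could be lost, and 403 and 335 of the 592 lower calls stayed. Loess kept 459 of the higher and 408 of the lower calls. No called gene passed the limit in the opposite direction in any setting run, although 6 changed sign with normexp. The number of genes with only a bound went from 65 to 36 with normexp, whose offset of 50 compresses low signals. Of 21 lists standing apart, 21 did so with normexp and 19 with quantile and with loess normalization. All 21 also did so with median and spike-in scaling, which shift lists and random lists alike and so could not change a call. The authors' table, also with 21, holds the same signal minus a constant for each array, so it is no separate check. Unmatched random lists kept 19 and the stricter filter 18, where the alpha-specific list had too few members. Without a filter on dim probes the glycolysis list lay at 0.028 instead of -0.51 from its random median, but this brings in genes saturated on both arrays, whose ratios show only the scaling. The UASINO, triacylglycerol and fatty acid lists kept their calls in every setting run. Of 197 named measured genes, none changed sign; 15 fell below 2-fold with normexp and 16 with spike-in scaling. The median over probes changed no count, as 28 genes have several probes. No paired analysis was possible because each group has 1 array. Signal over background limits the 65 bounds, whose true size is unknown.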

Other observations

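The genes and tests in this part were chosen after the first results were seen, except that the predictions for 6 of the 7 tests were written before their values were looked at; the test of nuclear genes against a weaker mutant array came after. The array carries 23 open reading frames of the mitochondrial genome, of which 16 were well above background in the wild type. In the mutant 14 of these were not well above background. Beside COB, COX1 and AI5_ALPHA, ATP8 was at least 219-fold lower, COX3 at least 126-fold, AI2 at least 125-fold, COX2 at least 40.8-fold and VAR1, a protein of the mitochondrial ribosome, at least 14.9-fold. OLI1 kept a signal of 74.3 in the mutant, against a saturated spot signal in the wild type. Q0017, described in the files as a dubious reading frame, was measured at -3.63 and -3.96, a ratio of -0.33. Genes often linked to retrograde signalling from mitochondria stayed within 2-fold, with CIT2 at 0.46, DLD3 at 0.10 and PDR5 at -0.53. CIT2 was already at 3.66 in the wild type and was at 4.125 in the mutant, where the saturated SNZ1 read 4.485. A 2-fold rise of CIT2 could therefore not have been recorded, and its value does not show that it was not induced.

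Neighbours of the deleted genes and of URA3, HIS3 and TRP1 were also read. Next to APP1, YNL095C was higher by 2.82 and YPT53 by 1.00, and next to LPP1, SAM2 was higher by 1.33. Near DPP1, MRX10 was higher by 1.09, and at TRP1, YDR008C was higher by 1.19. The YDR008C probe lies 1 bp from the TRP1 probe, so it is no separate neighbour, and it was dim, at -8.15 and -6.95. YEL023C, near URA3, was at -1.19, while the gene on either side of URA3, GEA2 at -0.66 and TIM9 at 0.50, lay within 2-fold. The neighbours of PAH1, MSS11 at -0.06 and MME1 at 0.46, lay within 2-fold. Beside HIS3, the probe of YOR203W, 315 bp from that of HIS3, was higher by 2.38 and DED1 by 0.73. Among all measured genes, 7.84% were at least 2-fold higher and 9.79% at least 2-fold lower. Median ratios of the 16 nuclear chromosomes ran from -0.21 for X to -0.02 for I, whereas an extra copy of a chromosome in a haploid would add about 1 to its genes if their RNA followed copy number. The probes of MATALPHA1 and HMLALPHA1, which share sequence, were higher by 2.08 each, and MATALPHA2 was higher by 1.42.

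Low a-specific and high alpha-specific genes may reflect a different mating type of the strains. Of 5 genes named before their values were seen, 3 went the expected way, but 2 of these, MF(ALPHA)2 and SAG1, belong to the alpha-specific list that is part of the pattern, and with normexp MF(ALPHA)2 was at 0.84, leaving a count of 2, which had been set as evidence against. Of the 3 a-specific genes only AGA2, at least 66.4-fold lower, did so, while STE6 at -0.46 and BAR1 at -0.23 did not. Since a count of 4 was required and the main setting gave 3, the test left the question open. Values outside that test went the way a different mating type would take: HMRA1 was at least 932-fold lower, and MATALPHA1 was higher by 2.08. They were not part of the prediction. A 2-fold fall of the whole mating pathway is argued against by 7 genes that both haploid types express. Their median was -0.66 (SE over these genes 0.18, not over cultures), above the -1 set for it, and they ran from -0.785 to 0.122. The median of all measured genes was -0.12, so a smaller fall of the pathway is not excluded. The labels give no mating type for the mutant.

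A defective spot is argued against for OLI1, since its 2 mutant spots differed by 0.11 on the log2 scale. Of 6071 nuclear genes with wild-type values from -9.24 to 4.15, the range of the mitochondrial genes, 1.29% were at least 4-fold lower. This decides nothing about a weaker signal over the whole mutant array, since scaling to the 75th percentile removes a uniform loss. Before scaling, the 75th percentile was a signal of 3758 in the wild type and 2962 in the mutant, and spike-in probes differed by -0.60. Both are far smaller than the OLI1 difference, so a uniform loss of that size is argued against. Loss of mitochondrial DNA from the mutant culture is a candidate explanation: 11 of 15 other mitochondrial probes were at least 4-fold lower, and 3 more were too dim in the wild type to show it. Q0017 was within 2-fold, which had been set as evidence against, but that bound was set too widely, as it took in 3 reading frames absent from the RefSeq gene table, Q0017, Q0297 and Q0182; without them 10 of 12 were at least 4-fold lower and 2 were too dim. The arrays measure RNA, so lost DNA and lost transcripts cannot be told apart here.

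URA3, HIS3 and TRP1 were high without their pathways. The other 16 genes of uracil, histidine and tryptophan synthesis had a median of -0.30 (SE over these genes 0.22, not over cultures), from -1.23 for URA1 to 1.47 for URA10. The lowest of the 3 ratios under quantile and loess normalization was 1.97. Those settings moved the median gene by only 0.10 and 0.11, so they could hardly have brought a ratio below the 1 set for scaling. Median and spike-in scaling add a constant to every ratio and could only raise them. What the values show is narrower: no scaling used here accounts for the 3 ratios. Copies of these genes used as markers to replace the deleted genes could give such values, but the labels do not say how the strain was built and this was not tested. Growth stage is likewise open, as each culture was sampled at the same 24 h and its density is not given in the sources used here.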
